A study of Ovis aries with 9 samples.

How the data were processed

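Sperm from the semen of F1 rams was profiled by small RNA sequencing. Per the labels' protocols, sperm were treated with a detergent buffer that lyses somatic cells, RNA was extracted with TRIzol, size-selected RNA was made into libraries with the NEBNext small RNA kit, and sequencing was done on an Illumina NovaSeq. The labels give 3 groups named after the feeding of the mothers, CON (standard), OVER (over feeding) and RES (restricted), with 3 samples each. The 9 files deposited by the authors are tables of distinct sequences, and per the file headers each row holds the sequence, its length, its count of reads, whether it matches the genome, and an annotation that can name several RNAs. The deposited read counts are whole numbers with no normalization. The submitters' processing notes name edgeR. The aligner, the annotation tool and the genome build are not given in the sources used here.

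The 3 deposited tables of each group were compared before use. After sorting, the sequences, the read counts and the genome flags were the same in all 3, and the set of annotation terms differed in 0 to 3 sequences. Whether a group's table is 1 library or a pool cannot be told from the files. Each group was therefore counted as 1 library, and the planned edgeR quasi-likelihood tests, permutation tests and gene set tests were replaced by values side by side. The designed fallback for a single sample per group was used: features were named by the largest log2 ratio of CPM among those with at least 100 reads in the 2 libraries together, 8 miRNAs, 5 tRNAs and 3 sequences in each direction, and the 10 miRNAs and 5 tRNAs highest in CON. The count of features at least 2-fold apart took the place of the count past a test threshold, a rule chosen after the tables were seen to be identical. Named sequences needed a mean CPM of at least 10. Sequences that did not match the genome or had no annotation were not named, since they could come from another organism. Some single sequences that this rule takes, among those lower in OVER, are not reported here.

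Each sequence was put into 1 class by its annotation, in the order miRNA, nuclear tRNA, mitochondrial tRNA, rRNA, Y RNA, misc RNA, small nuclear, small nucleolar, long non-coding and other RNA, and reads annotated only as antisense were kept apart. Class shares are percentages of annotated reads. Reads of a sequence with several miRNA or tRNA names were given in full to each, and all ends of a tRNA were summed. Counts were scaled within the miRNA class, within nuclear plus mitochondrial tRNAs, and over all sequences by edgeR's TMM, which assumes that most features of a class are alike between libraries. CPM is then counts scaled by the TMM-scaled class total, and RPM is scaled by all reads of the library with no TMM factor. Intervals of shares are exact Clopper-Pearson 95% intervals, and those of log2 ratios come from the exact binomial interval of the 2 counts. A count of 0 was set to 3 reads. In shares of all reads, 3 reads are 3.00e-05% of the CON library, 3.62e-05% of OVER and 2.28e-05% of RES.

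Lists of miRNAs, tRNAs, rRNA species and Y RNAs, 12 in all, were fixed before the data were examined. For each list with at least 3 measured members the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean CPM in 3 bins. Ovine miRNA names were looked up in a RefSeq gene table of assembly ARS-UI_Ramb_v3.0, in which 105 of 105 names were found. Its coordinates are not printed, since the build of the files is unknown. After the files were seen, miRNA reads without an ovine name were searched for 35 known mature sequences by their first 18 nt, and 5′ fragments of 6 tRNAs and 2 Y RNAs were counted by their first bases, for tRNA-Glu-CTC and tRNA-Gly-GCC also with bases deleted. Matches to 7SL, U2, 5S and 28S RNA were found by shared stretches of 14 nt. The shared response of OVER and RES was set beside 100 simulations of unchanged libraries.

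The alternatives were DESeq2 size factors, all reads as the library size, factors from the 2 libraries compared only, no filter beyond 1 read, windows of 16 to 24 nt for miRNAs and 25 to 40 nt for tRNAs, genome-matching sequences only, and an equal split of reads with several names. For class shares they were all reads as the denominator and no sequences of several classes. The ratio calculation was tested on simulated counts for OVER against CON over 5780 sequences, 200 of them changed. The counts were drawn with an assumed spread between libraries (dispersion 0.05) that no replicate here can check. The simulated shares are therefore not error rates of the real comparison. The mean log2 ratio recovered was 0.89 and -0.81 for 2-fold changes and 2.02 and -1.90 for 4-fold changes, and 4.46% of unchanged sequences came out at least 2-fold apart. A first limit on this test, a median within 0.1 of the truth, was missed for the 2-fold changes (0.86 and -0.71) and was replaced by one on the mean. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 were used.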

Results

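Small RNA was sequenced from the sperm of F1 rams, the sons of ewes that had been fed a standard diet (CON), had been overfed (OVER) or had been kept on restricted feed (RES). The series asks whether the mother's nutrition during gestation is seen in the small RNAs of her sons' sperm. Per the labels, each group has 3 samples, 9 in all, but within each group the 3 tables held the same sequences with the same read numbers. Each group was therefore counted as 1 library. Whether it is a single library or a pool cannot be told. No difference below has a replicate check, no test between groups was possible, and every interval covers counting error only. The CON library held 9983895 reads of 1311597 distinct sequences, the OVER library 8287937 reads of 1296002 sequences and the RES library 13160116 reads of 1249810 sequences. Reads were 15 to 42 nt long. The annotated share of reads was 57.6% in CON, 62.9% in OVER and 67.6% in RES.

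The OVER library differed from the other libraries in the size of its RNA. Mean read length was 23.3 nt in OVER, against 28.5 nt in CON and 27.2 nt in RES. Reads of 15 to 20 nt made up 29.6% of the OVER library, 5.98% of the CON library and 10.3% of the RES library. The 29 to 33 nt range, in which 5′ fragments of tRNAs and Y RNAs lie, held 19.9% of OVER reads, 47.1% of CON reads and 41.5% of RES reads. The same direction was seen inside classes of RNA. The 15 to 20 nt share of rRNA reads was 46.2% in OVER and 10.5% in CON, and that of nuclear tRNA reads was 6.03% in OVER and 0.511% in CON. The mean length of miRNA reads, which are cut to a fixed size by Dicer, was 22.03 nt in OVER, 22.6 nt in CON and 22.4 nt in RES.

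**Figure D1:**
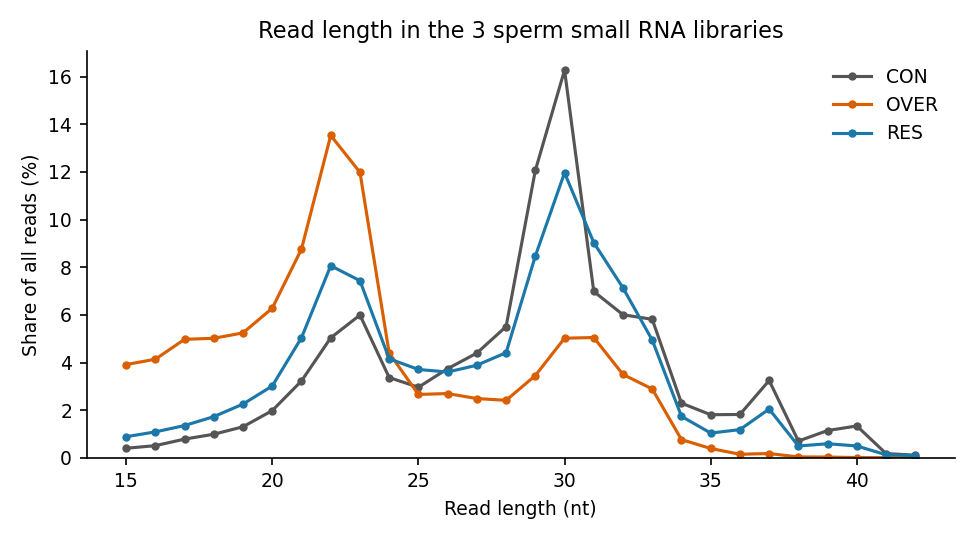
Share of all reads (%, y axis) at each read length (nt, x axis) in the CON, OVER and RES libraries, 1 line per library. The CON and RES libraries peak at 30 nt with 16.3% and 11.96% of reads, and the OVER library peaks at 22 nt with 13.5%.

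Fragments of nuclear tRNAs, the most abundant annotated class in control sperm, took a smaller share of the OVER library, and miRNAs took a larger one. Nuclear tRNAs held 44.9% of annotated reads in CON (exact Clopper-Pearson 95% interval 44.87 to 44.95%) and 19.3% in OVER (19.31 to 19.37%), a share 2.32-fold lower. The miRNA share was 14.6% in CON (14.57 to 14.62%) and 26.5% in OVER (26.46 to 26.54%), 1.82-fold higher. Y RNAs, small cytoplasmic RNAs bound by the Ro60 protein, held 12.9% of annotated reads in CON and 6.62% in OVER. The class named misc RNA held 7.54% in CON and 22.2% in OVER, and 77.3% of it in CON and 69.1% of it in OVER shared 14 nt or more with 7SL RNA, the RNA of the signal recognition particle. Small nuclear RNAs held 1.45% in CON and 6.68% in OVER, 4.59-fold higher, and 76.3% of these reads in OVER shared 14 nt or more with U2, a part of the spliceosome. Since shares of 1 library sum to the whole, these values move together. CON reads given the lengths of the OVER reads would hold 16.9% tRNA, 33.9% miRNA, 5.36% small nuclear RNA, 8.27% Y RNA and 9.96% misc RNA. The OVER share was 1.15 times this value for tRNA, 0.781 times for miRNA, 1.24 times for small nuclear RNA, 0.801 times for Y RNA and 2.23 times for misc RNA.

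In the RES library the tRNA share was also lower than in CON, and the Y RNA share was higher. Nuclear tRNAs held 24.9% of annotated RES reads (24.88 to 24.94%), 1.80-fold lower than in CON, and Y RNAs held 22.8% (22.81 to 22.87%), 1.78-fold higher. The miRNA share was 17.2%, 1.18-fold higher than in CON, and 0.880 times the share of CON reads given the RES lengths. Those CON reads would hold 33.7% tRNA and 15.3% Y RNA. The RES share was 0.740 times this value for tRNA and 1.49 times for Y RNA, both closer to CON than the plain shares. Small nucleolar RNAs, guides for rRNA modification, held 0.240% in CON, 0.193% in OVER and 0.0595% in RES. Mitochondrial tRNAs held 1.20%, 1.33% and 1.41% of annotated reads in CON, OVER and RES. Between the diet groups, the OVER library held a tRNA share 1.29-fold lower, a Y RNA share 3.45-fold lower, an miRNA share 1.54-fold higher and a small nuclear RNA share 5.11-fold higher than the RES library. Against RES reads given the OVER lengths, the directions turn for tRNA (1.51 times the value) and miRNA (0.891 times). The Y RNA share was then 0.532 times the value and the small nuclear RNA share 2.13 times, both closer to RES than the plain shares.

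Among rRNA species, mitochondrial rRNA was the one that differed most between CON and RES. It held 3.22% of annotated reads in CON, 2.63% in OVER and 6.39% in RES. The 28S species held 5.19%, 5.76% and 6.12% in the same order, 18S 3.56%, 3.28% and 2.85%, 5S 0.537%, 0.371% and 0.508%, and 5.8S 0.0157%, 0.0253% and 0.0157%. The Y RNAs are given in the files as 1 class, so 2 of their 5′ fragments were counted by their first bases. The Y1 5′ fragment stood at 68107 RPM (reads scaled to all reads of the library) in CON, 37234 in OVER and 148083 in RES. The Y4 5′ fragment went the other way in RES, with 2176 RPM in CON, 1594 in OVER and 222.2 in RES, which is 9.79-fold lower than in CON. The 2 Y RNA fragments had similar lengths in every library, with 97.2 to 98.8% of their reads at 31 to 34 nt.

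**Figure D2:**
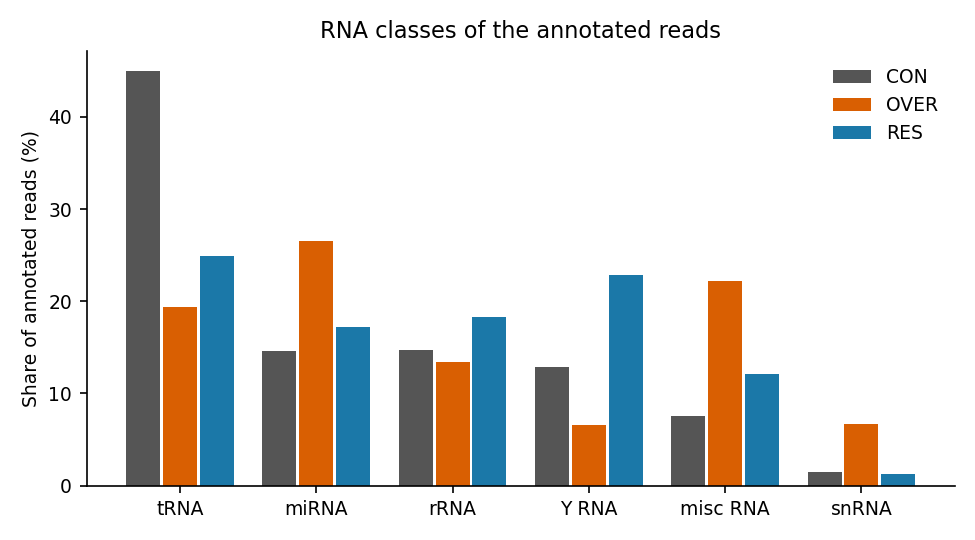
Share of annotated reads (%, y axis) of 6 RNA classes (x axis) in the CON, OVER and RES libraries, 1 bar per library. Counting intervals are narrower than the bar outlines. The tRNA share is 44.9% in CON, 19.3% in OVER and 24.9% in RES, and the Y RNA share is 12.9%, 6.62% and 22.8%.

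In the OVER library, fragments of the glutamate and proline tRNAs were lower than in CON and fragments of alanine and threonine tRNAs were higher. The arginine tRNAs went both ways, from Arg-CCT (log2 ratio -0.63) to Arg-TCT (2.41). Nuclear and mitochondrial tRNA reads were scaled within the tRNA class by edgeR's trimmed mean of M values (TMM), and 70 tRNAs with at least 100 reads in the 2 libraries together were compared. By this measure 14 tRNAs were at least 2-fold higher in OVER and 11 at least 2-fold lower, and 45 lay within 2-fold. The 5 largest ratios were those of mt-Ala-TGC, at 44.5 CPM (counts scaled to the class total) in CON and 357 CPM in OVER (8.02-fold higher, log2 interval 2.66 to 3.37), Thr-TGT (log2 ratio 2.69), Arg-TCT, Ala-TGC (2.24) and Ala-CGC (2.23). The 5 lowest were Glu-CTC, with 593980 CPM in CON and 37158 CPM in OVER (log2 ratio -4.00, -4.01 to -3.99), Pro-CGG (-2.76), Pro-AGG (-2.75), Pro-TGG (-2.73) and Glu-TTC (-2.64). Much of this rests on reads given to more than 1 tRNA: 99.9% of the Pro-CGG reads, 95.7% of the Ala-TGC reads, 94.6% of the Thr-TGT reads and 77.8% of the Glu-TTC reads also carried the name of another tRNA, so isoacceptors such as the 3 proline tRNAs are not separate observations. Scaling to all reads in place of tRNA reads shifts the median of the tRNAs by 0.38 log2, and the split is then 25 higher and 7 lower. With reads of 25 to 40 nt only, 4 of 58 tRNAs were at least 2-fold higher and 15 lower, Arg-TCT was no longer 2-fold higher (log2 ratio 0.46), and mt-Ala-TGC (1.68) and Ala-TGC (1.81) were closer to CON.

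With 5′ fragments counted by their first bases, which differ between the 2 glutamate tRNAs, the OVER difference was large for tRNA-Glu-CTC and small for tRNA-Glu-TTC. The Glu-CTC 5′ fragment had 96090 RPM in CON, 6437 in OVER and 43336 in RES, 14.9-fold lower in OVER and 2.22-fold lower in RES. With the forms that carry deletions added, it was 6.68-fold lower in OVER and 2.20-fold lower in RES. The Glu-TTC 5′ fragment had 14598, 10486 and 8832 RPM. The Gly-GCC 5′ fragment had 36194, 26951 and 21524 RPM and the His-GTG 5′ fragment 45387, 26989 and 42559. The Lys-CTT 5′ fragment was 1.48-fold higher in OVER than in CON and 5.47-fold lower in RES, at 811.2, 1199 and 148.3 RPM.

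The ends of some of these fragments lay elsewhere in the OVER library. The commonest length of the Gly-GCC 5′ fragment was 31 nt in OVER and 30 nt in CON and RES, and reads of 31 to 34 nt made up 72.8% of it in OVER, 27.9% in CON and 12.3% in RES. For Glu-TTC the commonest length was 33 nt in OVER and 30 nt in CON and RES, and for His-GTG it was 30 nt in all 3. Taking all nuclear tRNA reads, 76.7% carried a 5′ end name in CON, 64.2% in OVER and 66.4% in RES, and 0.385 to 0.545% reached the 3′ CCA end.

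**Figure D3:**
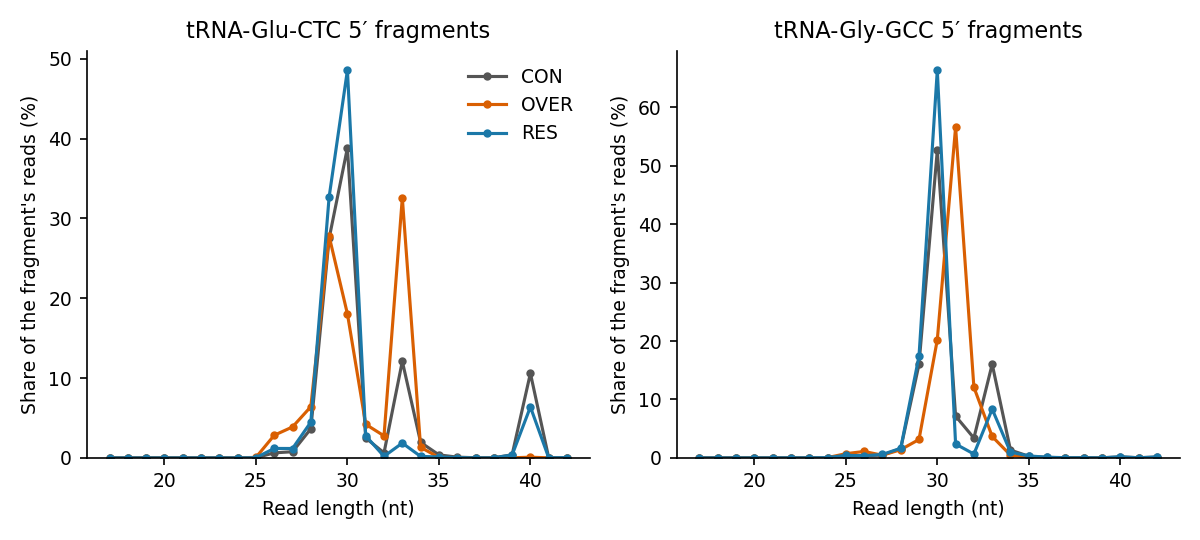
Length (nt, x axis) of the tRNA-Glu-CTC and tRNA-Gly-GCC 5′ fragments without deletions, as a share of that fragment's reads (%, y axis), 1 line per library. The CON and RES lines peak at 30 nt in both panels, and the OVER line peaks at 33 nt for Glu-CTC and 31 nt for Gly-GCC.

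The tRNAs whose sperm fragments moved with paternal diet in rodent studies, a list of 10 fixed before the data were examined, were mostly lower in both diet groups. In OVER, 8 of the 10 were below CON and 3 of these at least 2-fold, with Lys-CTT (log2 ratio 0.68) and Lys-TTT (0.34) above. The list's median log2 ratio was -0.60, at percentile 34.9 of 10000 random lists of tRNAs matched on mean abundance. In RPM, 6 of the 10 were lower and the median was -0.22. In RES all 10 were at or below CON, with a median of -0.64 at percentile 5.87, and in RPM the median was -0.68. Val-AAC (-0.004) and Val-CAC (-6.3e-05) were level with CON there. The 10 are not separate observations, which limits these counts and percentiles. Another name was also carried by 98.1 to 99.6% of the reads of the glycine tRNAs. The same held for 99.8 to 99.9% of those of Val-AAC and Val-CAC, 84.8% of Glu-CTC and 77.8% of Glu-TTC. The 18 mitochondrial tRNAs compared had medians of 0.11 (percentile 2.67) in OVER and 0.12 (percentile 50.1) in RES against CON.

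The RES library differed less from CON in its tRNAs than the OVER library did. Of 70 tRNAs compared, 5 were at least 2-fold higher, 1 was at least 2-fold lower and 64 lay within 2-fold. The higher ones were Leu-TAA (689.4 CPM in CON and 1930 CPM in RES, log2 ratio 1.49, 1.39 to 1.58), Arg-TCG (1.37), mt-Phe-GAA (1.36), mt-Cys-GCA (1.33) and mt-Ala-TGC (1.09). The lowest were Glu-CTC (log2 ratio -1.09), Pro-TGG (-0.98), Pro-CGG (-0.97), Pro-AGG (-0.97) and Glu-TTC (-0.94). With reads of 25 to 40 nt only, Leu-TAA (log2 ratio 0.52), Arg-TCG (0.60) and Glu-CTC (-0.41) lay within 2-fold. With DESeq2 size factors the split was 4 higher and 6 lower, and in RPM 5 higher and 4 lower. Between OVER and RES, 12 tRNAs were at least 2-fold higher in OVER and 10 in RES, out of 71. The highest in OVER were Thr-TGT (log2 ratio 2.67), Arg-TCT (3.90-fold), mt-Ala-TGC (1.91), Ala-CGC (1.73) and Ala-TGC (1.72), and the lowest were Glu-CTC (-2.91), mt-Ser-TGA (-2.28), Pro-CGG (-1.78), Pro-AGG (-1.78) and mt-Phe-GAA (-1.77). In RPM that split was 20 higher and 7 lower, after a shift of the median of 0.41 log2, and with reads of 25 to 40 nt only it was 4 higher and 20 lower.

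In control sperm, the most abundant miRNA among those with an ovine name was oar-mir-21, at 215547 CPM of the miRNA class. The others of the 10 highest with an ovine name were oar-mir-99a at 111910 CPM, oar-mir-148a at 60584, oar-mir-191 at 49930, oar-mir-30a at 32718, oar-mir-30d at 30085, oar-mir-10a at 25092, oar-mir-10b at 23388, oar-let-7a at 16688 and oar-mir-26a at 16685. Of the reads named oar-mir-99a, 95.1% in CON, 96.9% in OVER and 99.2% in RES carried the mature sequence of its family member miR-100. Between 34.3% and 40.9% of the miRNA reads had no ovine miRNA name, and some of these were named here by the first 18 nt of known mature sequences. The most abundant of the miRNAs named in this way were miR-100, at 87469 CPM in CON, which comes on top of the miR-100 reads named oar-mir-99a, and miR-34c, a miRNA of meiotic and later male germ cells, at 67357 CPM. The 5 highest tRNAs in CON were Glu-CTC, Glu-TTC, His-GTG, Gly-GCC and Gly-CCC, at 593980, 585902, 450698, 241265 and 236975 CPM of the tRNA class. Reads with several names count in full for each, and by first bases the Glu-TTC 5′ fragment lay below those of Glu-CTC, His-GTG and Gly-GCC.

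Within the miRNA class, the OVER library held less of the let-7 family, which blocks growth-promoting mRNAs in differentiated cells, than the CON library, and more of miR-30b, miR-127, miR-152 and miR-22. Of 76 miRNAs compared, 8 were at least 2-fold higher in OVER, 7 were at least 2-fold lower and 61 lay within 2-fold. All 8 higher ones are named by the size rule: oar-mir-30b (1123 CPM in CON and 4871 CPM in OVER, log2 ratio 2.12, 2.02 to 2.22), oar-mir-127 (314 and 1054 CPM, 1.75, 1.56 to 1.94), oar-mir-152 (1.37), oar-mir-380 (1.28), oar-mir-412 (1.20), oar-mir-376b (1.18), oar-mir-22 (1.05) and oar-mir-376c (1.01). The 8 lowest were oar-mir-543 (1113 and 265.3 CPM, -2.07, -2.23 to -1.91), oar-mir-16b (13004 and 3605 CPM, -1.85, -1.90 to -1.81), oar-let-7f (-1.46), oar-let-7a (-1.40), oar-let-7c (-1.17), oar-mir-103 (-1.16), oar-mir-107 (-1.12) and oar-mir-323a (-0.90). The counting intervals of oar-mir-376b (0.55 to 1.87) and oar-mir-376c (0.53 to 1.52) were wide. The whole miRNA class was larger in OVER, so in RPM the median miRNA shifts by 1.248 log2 and the split becomes 49 at least 2-fold higher and 0 at least 2-fold lower. The ratios above are therefore relative to other miRNAs.

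Of the miRNA lists fixed in advance, let-7 stood furthest from random lists in OVER against CON. All 7 measured members were below CON within the class, 3 of them at least 2-fold, and the median log2 ratio was -0.75, at percentile 0.72 of 10000 random lists. The 3, oar-let-7a, oar-let-7c and oar-let-7f, share 92.8 to 99.8% of their reads with other names, and the intervals of oar-let-7b (-0.13 to 0.11) and oar-let-7i (-0.11 to 0.03) include 0. That direction turns in RPM, where 5 of the 7 were higher and the median was 0.50, below the shift of all miRNAs. Of the 31 measured miRNAs of the imprinted DLK1-DIO3 domain, a cluster expressed from the maternal chromosome, 21 were above CON and 10 below, 5 were at least 2-fold higher and 1 at least 2-fold lower, and the median was 0.26 at percentile 82.1. The 5 were oar-mir-127, oar-mir-380, oar-mir-412, oar-mir-376b, of whose reads 99.5% carried another name as well, and oar-mir-376c, which was below 2-fold with DESeq2 size factors (log2 ratio 0.98) and with shared reads split equally (0.87). The 4 measured germ line miRNAs had a median of -0.57 (percentile 23.1), with oar-mir-22 the only one above CON, the 5 of the miR-17-92 family had a median of 0.00 (percentile 51.5), and the 11 metabolic miRNAs had a median of -0.40 (percentile 5.20), with oar-mir-103 and oar-mir-107, regulators of insulin sensitivity, at least 2-fold lower, with 79.0 and 99.2% of their reads under another name as well, and oar-mir-30b at least 2-fold higher. The 3 measured epithelial miRNAs, oar-mir-200a, oar-mir-200b and oar-mir-200c, lay close to CON, with log2 ratios of 0.15, 0.05 and -0.23. Of the 4 blood cell entries named by sequence, 3 were below CON and 1 above, with a median of -0.58. The lowest was the miR-223 5′ arm, 3.49-fold lower (-1.80, -1.95 to -1.65), and the 3′ arm stood at -0.56. These list values are within the class, and in RPM the germ line and metabolic medians turn to 0.68 and 0.84.

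The RES library held less of the miR-200 family of epithelia and of miR-223 of white blood cells than the CON library, and more of miR-451 and miR-486 of red blood cells. Oar-mir-200a, oar-mir-200b and oar-mir-200c, which maintain the epithelial state, were 2.64-fold, 4.44-fold and 5.40-fold lower, with log2 ratios of -1.40 (-1.52 to -1.28), -2.15 (-2.31 to -1.99) and -2.43 (-2.59 to -2.28). MiR-223, the leading miRNA of neutrophils, was 52.4-fold lower for its 3′ arm (364 reads in CON, 10 in RES) and 74.98-fold lower for its 5′ arm (1041 reads in CON, 20 in RES). MiR-142-3p, a miRNA of blood cells in general, had 47 reads in CON, 61 in OVER and 1 in RES. MiR-451, which matures during red cell development, had 3 reads in CON, 7 in OVER and 1722 in RES, a log2 ratio of 8.64 (7.09 to 10.92) against CON. MiR-486, also abundant in red cells, had 7 reads in CON, 4 in OVER and 2150 in RES, with a log2 ratio of 7.74 (6.69 to 9.05). MiR-144, the third red cell miRNA of the list, had 0 reads in all 3 libraries among the miRNA reads without an ovine name. Unannotated reads were not searched for it, so its absence was not shown. MiR-146b of the same blood cell list was 1.56-fold higher in RES (16953 CPM in CON and 26438 CPM in RES). The sperm had been treated to lyse somatic cells, per the labels. The blood cell miRNAs were named by sequence, a step added after the files were seen.

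**Figure D4:**
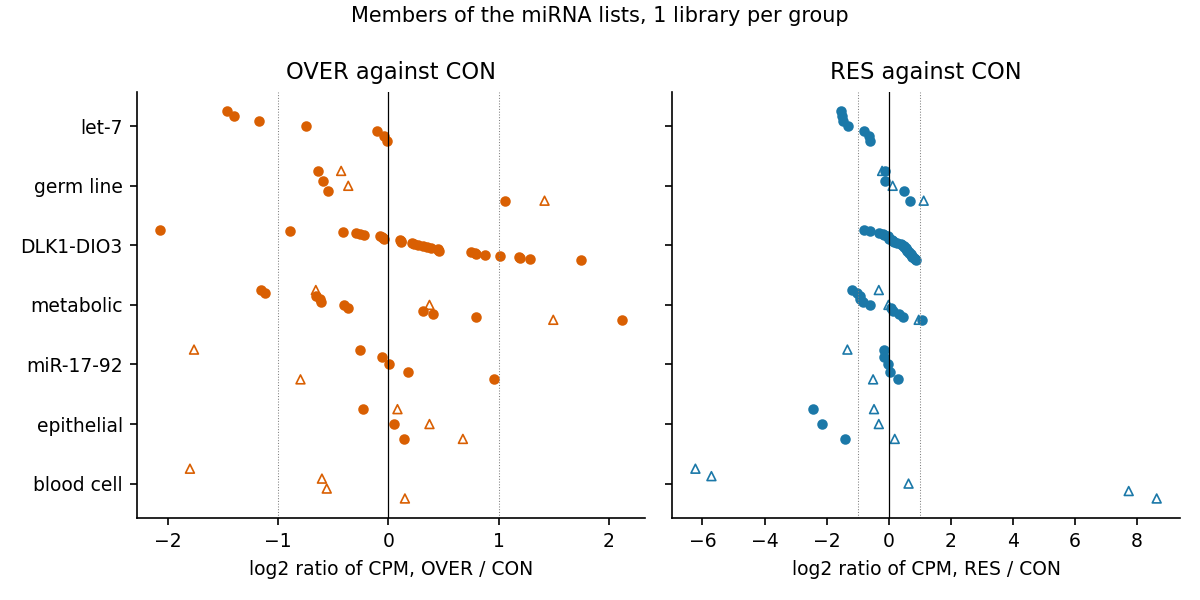
Log2 ratio of CPM (x axis) of each list member with at least 100 reads in the 2 libraries, for OVER against CON and RES against CON, 1 library per group. Rows are lists, filled circles are miRNAs named in the annotation, open triangles are those named by mature sequence, and dotted lines mark 2-fold. In RES the blood cell row runs from -6.23 for the miR-223 5′ arm to 8.64 for miR-451, and the x axes of the panels differ in range.

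Of 74 miRNAs compared between RES and CON, 2 were at least 2-fold higher, 14 were at least 2-fold lower and 58 lay within 2-fold. The higher ones were oar-mir-148a (60584 CPM in CON and 145015 CPM in RES, log2 ratio 1.26) and oar-mir-30b (1.06, 0.95 to 1.17). They were followed by 6 miRNAs of the DLK1-DIO3 domain, oar-mir-3958 (0.89), oar-mir-323a (0.83), oar-mir-487a (0.82), oar-mir-411b (0.75), oar-mir-655 (0.74) and oar-mir-154a (0.73). The 8 lowest were oar-mir-181a-2 (log2 ratio -2.82, from 93 and 19 reads), oar-mir-221 (468.2 and 67.4 CPM, -2.80, -3.15 to -2.45), oar-mir-181a-1 (-2.54, from 89 and 22 reads), oar-mir-200c, oar-mir-200b, oar-let-7f (-1.55), oar-let-7a (-1.50) and oar-let-7b (-1.47). Of the reads of oar-mir-181a-2, 95.3% also carried another name, which for this pair is the other copy of the same miRNA.

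The let-7 family and the DLK1-DIO3 domain lay at the lowest and highest percentile among random lists in RES against CON. All 7 let-7 members were lower, 4 of them at least 2-fold, with a median log2 ratio of -1.30 at percentile 0.205, and all 7 stayed lower in RPM (median -1.17). The 4, oar-let-7a, oar-let-7b, oar-let-7c and oar-let-7f, share 92.7 to 99.8% of their reads with other names. They are therefore not separate observations, which limits the count and the percentile. Of 30 measured DLK1-DIO3 miRNAs, 23 were above CON and 7 below, none by 2-fold, with a median of 0.46 at percentile 99.9. Some of them share most of their reads with other names, such as oar-mir-329a (99.8%), oar-mir-376d (95.9%) and oar-mir-376e (98.6%). Others, such as oar-mir-3958, share none. The 30 are therefore not all separate observations, and they are a large part of the 74 miRNAs from which random lists were drawn. The gene table used for names, of assembly ARS-UI_Ramb_v3.0, places all 53 miRNAs of this list found here between the genes DLK1 and DIO3. The epithelial list had a median of -2.15 at percentile 2.40, from 3 members. Of the oar-mir-200b and oar-mir-200c reads, 53.6 and 47.7% also carried another name, so these 2 are not separate observations. With miR-375, miR-182 and miR-183 added by sequence, 5 of 6 were lower and the median was -0.93. The 11 metabolic miRNAs had a median of -0.62 (percentile 6.40), or -0.16 over 14 with those named by sequence, the 5 of the miR-17-92 family -0.02 (percentile 49.65) and the 4 germ line miRNAs 0.20 (percentile 71.7). Of the muscle, vessel and stromal list, oar-mir-143 alone passed the read minimum by name, with 79 reads in CON and 50 in RES (log2 ratio -1.19, -1.73 to -0.66). MiR-126 of the same list, named by sequence, had 39 reads in CON, 121 in OVER and 59 in RES.

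Set against each other, the diet groups differed in 22 of 80 miRNAs by at least 2-fold, 15 higher in OVER and 7 higher in RES. The 8 highest in OVER were oar-mir-127 (1054 CPM in OVER and 182.8 CPM in RES, log2 ratio 2.53, 2.33 to 2.73), oar-mir-221 (2.46), oar-mir-181a-2 (2.46), oar-mir-200b (2.20), oar-mir-200c (2.20), oar-mir-181a-1 (2.19), oar-mir-26b (1.82) and oar-mir-23a (1.78). Another name was also carried by 95.3 and 98.0% of the oar-mir-181a-2 and oar-mir-181a-1 reads, 86.0% of oar-mir-26b and 95.1% of oar-mir-23a. The same held for 53.6 and 47.7% of the oar-mir-200b and oar-mir-200c reads, and for none of oar-mir-127 and oar-mir-221. The 8 are therefore not all separate observations. The 8 lowest were oar-mir-323b (-2.26), oar-mir-543 (-2.09), oar-mir-16b (-1.82), oar-mir-323a (-1.73), oar-mir-191 (32096 and 80960 CPM, -1.33), oar-mir-99a (-1.06), oar-mir-125b (-1.06) and oar-mir-329b (-0.94). In RPM the median shifts by 1.12 log2 and the split is 52 higher and 1 lower, with oar-mir-99a, oar-mir-125b and oar-mir-329b then slightly higher in OVER. The epithelial list had a median of 2.20 (percentile 99.6), let-7 of 0.13 (percentile 65.6), DLK1-DIO3 of -0.10 (percentile 0.735), the germ line list of -0.45 (percentile 16.6), the metabolic list of -0.00 (percentile 34.98) and the miR-17-92 list of -0.04 (percentile 34.98). The rodent diet tRNAs had a median of -0.06 (percentile 97.8) and the mitochondrial tRNAs of 0.03 (percentile 6.795), which turned to -0.99 with reads of 25 to 40 nt only. In RPM the medians of the DLK1-DIO3, germ line, metabolic and miR-17-92 lists turn to 1.02, 0.67, 1.12 and 1.08, and that of the rodent diet tRNAs to 0.35. MiR-451 and miR-486 were 337-fold and 736-fold lower in OVER than in RES.

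The single sequences named here match the genome, carry an annotation and reach the mean CPM set for naming. The counts of sequences are not limited in this way. These rules for naming left out 5 of the sequences with the largest ratios in OVER against CON. They also left out 5 in RES against CON and 2 in OVER against RES. The sequences named are therefore not those with the largest ratios of all. Of 9319 sequences with at least 100 reads in OVER and CON together, 3190 were at least 2-fold higher in OVER and 3271 at least 2-fold lower. The highest given next are among sequences that meet the rules for naming. The highest in OVER against CON were short pieces: GACGAGGTGGCCGAG of tRNA-Ser-GCT with 1 read in CON and 292 in OVER (8.43, 5.94 to 13.74), GATGTAAGATGTAGTCTT of mt-Ala-TGC with 1 and 241 (8.16, 5.66 to 13.47), and GCCTGTAGTCCCAGC, annotated as misc RNA, with 2 and 355 (7.72, 5.85 to 10.77).

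Between RES and CON, 3014 of 11737 sequences were at least 2-fold higher in RES and 1739 at least 2-fold lower. The highest and lowest given next are among sequences that meet the rules for naming. The highest were AAACCGTTACCATTACTGAGT, a read of miR-451, with 2 reads in CON and 1243 in RES (log2 ratio 8.84, 6.98 to 11.88), and the miR-486 reads TCCTGTACTGAGCTGCCCCGAGT (3 and 856 reads, 7.71, 6.16 to 9.99) and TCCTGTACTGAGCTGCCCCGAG (2 and 497 reads, 7.51, 5.65 to 10.56). The lowest were TACCCGGTAGATCCGAATTTGT, named oar-mir-10a, with 356 reads in CON and 3 in RES (-7.33, -9.62 to -5.77), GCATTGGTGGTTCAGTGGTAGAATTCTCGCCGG of tRNA-Gly-GCC with 409 and 5 (-6.80, -8.43 to -5.56), and the miR-223 5′ arm TGTGTATTTGACAAGCTGAGTTG with 529 and 9 (-6.32, -7.46 to -5.38). The read named oar-mir-10a differs in 1 base from the leading sequence of that name. As a whole, oar-mir-10a lay close to CON in RES, at 25092 CPM of the miRNA class in CON and 22931 in RES (log2 ratio -0.13). Between OVER and RES, 2896 of 11256 sequences were at least 2-fold higher in OVER and 4215 at least 2-fold lower. Those given next are again among sequences that meet the rules for naming. The highest were CAGTCGGTAGAGCATCAGACT, shared by lysine and arginine tRNAs, with 376 reads in OVER and 1 in RES (9.24, 6.75 to 14.55), AGCGGTTAGGATTCCTGGTT of tRNA-Glu-TTC with 278 and 1 (8.81, 6.32 to 14.11), and AGGATTGACAGACTG of 18S rRNA with 274 and 2 (7.78, 5.92 to 10.84). Lower in OVER was the 28S piece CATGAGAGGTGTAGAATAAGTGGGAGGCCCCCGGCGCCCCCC with 1 read in OVER and 611 in RES (-8.57, -13.87 to -6.09).

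Whether OVER and RES depart from CON in the same way was examined over features, which are not independent replicates. Both comparisons use the same CON library, which alone gives a correlation, so unchanged libraries were simulated with the spread between features seen here. Over 73 miRNAs, Pearson's r between the log2 ratios was 0.34 and Spearman's rho 0.39, against a simulated r of 0.50 (95% range 0.32 to 0.65). Over 70 tRNAs r was 0.65 and rho 0.68, against 0.49 (0.30 to 0.66). Over 7949 sequences r was 0.57 and rho 0.60, against 0.50 (0.48 to 0.52), with a covariance of 2.14 beside a simulated 2.16. The covariance was 0.25 beside 0.43 for miRNAs and 0.53 beside 0.55 for tRNAs. Over the 5244 sequences with a mean CPM of at least 10, r was 0.50 and lay inside the simulated range (0.48 to 0.52). Of the miRNAs, oar-mir-30b was at least 2-fold higher in both, and oar-let-7a, oar-let-7c and oar-let-7f, which share most of their reads, were at least 2-fold lower in both. The directions were opposite at 2-fold in 0 of the 73 miRNAs, 0 of the 70 tRNAs and 289 of the 7949 sequences. The CON library could not be split, as it is 1 library.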

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

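The explanations below were tested after the patterns had been seen, and of the tests only the one that gives CON reads the lengths of OVER reads had its expected outcome written before its result was known. For the third pattern, a test on the red cell miRNAs alone (median 8.19) and one on the median of the blood cell list (0.64) were run first and set aside, the first because its members were picked after their ratios had been seen and the second because a median of members that go both ways decides nothing. The test used, whether all members move alike, was written with all these values known. Among reads outside the annotated counts by feature, 3 kinds made up a larger share of their fragment or class in OVER or RES than in CON. Reads of the tRNA-Glu-CTC 5′ fragment with 1 or 3 bases missing near the 5′ end are for the most part not named by the annotation. They made up 72.4% of all forms of this fragment in OVER and 39.0% in RES, against 38.5% in CON. In RPM they were not raised. Forms with 1 base missing had 32196 RPM in CON, 5685 in OVER and 12898 in RES. Those with 3 missing had 27835, 11243 and 14770 RPM. The higher share in OVER goes with the larger fall of the intact form, from 96090 to 6437 RPM. Mature miRNA sequences with 1 to 4 A added at the 3′ end made up 8.13% of miRNA reads with and without that tail in RES, against 6.66% in CON and 4.22% in OVER, and tails of T made up 0.515 to 0.688%. Reads annotated only as antisense to a known RNA made up 1.33% of annotated reads in OVER, against 0.644% in CON and 0.437% in RES. Of these antisense reads, 65.3% in OVER, 26.4% in CON and 57.6% in RES were 15 to 20 nt long. The higher share in OVER was therefore not separated from the larger number of short reads in that library.

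The first pattern weighed is the low tRNA share of the OVER library, 19.3% of annotated reads against 44.9% in CON. If longer inserts had been lost with no other difference, CON reads given the lengths of the OVER reads would show the OVER share. They gave 16.9%, and the OVER share was 1.15 times that value, outside the 10% band set beforehand for this explanation and inside the 25% limit that would have excluded it. The length of a read and its class are tied, since a library with fewer tRNA fragments also has fewer 30 nt reads, so loss of long inserts, breakage of RNA and less tRNA cleavage cannot be told apart for the tRNA share. Over feeding of the mother is the biological explanation the design names, and with 1 library per group it stays open as well.

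The second pattern is the lower tRNA-Glu-CTC 5′ fragment in OVER. Of the technical explanations tested, the deleted forms are argued against, and loss of long inserts is not settled by its test. With the unannotated deleted forms added, the log2 ratio against CON was -2.74, less than the -3.90 of intact reads but far from 0. Loss of long inserts would lower fragments of equal length alike. At 28 to 34 nt the log2 ratio of Glu-CTC was 3.37 lower than that of Gly-GCC (difference -3.37) for intact reads. With deleted forms it was 2.44 lower (difference -2.44). This window spans several lengths, and the commonest Gly-GCC length moved within it, from 30 nt in CON to 31 nt in OVER. At 33 nt intact reads fell alike, from 116002 in CON to 17383 in OVER for Glu-CTC and from 57942 to 8164 for Gly-GCC. At 30 nt Glu-CTC fell further, from 372561 to 9623 reads, against 190259 to 45144. The gap thus depends on the length taken, so the window cannot settle this explanation. What stays open is loss of long inserts, a difference in the tRNA cleavage of the rams' sperm or epididymis, or handling of the sample. A step of the library preparation that favours some sequences stays open too. None of these can be separated with 1 library per group.

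The third pattern is the low level of epithelial miRNAs in RES, with a median log2 ratio of -2.15 over the 3 miR-200 members and -0.93 over 6 with miR-375, miR-182 and miR-183 added, so it is mainly one of the miR-200 family. Scaling does not account for it, since the median in RPM was -2.02. Fewer somatic cells of every kind would lower blood cell miRNAs as well, but those named by sequence parted, with a gap of 11.5 log2 between the intervals of miR-451 and miR-486 (log2 ratios 8.64 and 7.74) and those of the miR-223 arms (-5.71 and -6.23), and with miR-146b at 0.64. The rule for this test was written with these values known, so its outcome was fixed, and the miR-223 arms are 1 miRNA. Higher miR-451 and miR-486 are not what fewer red cells would give. A loss of every kind of cell other than red cells cannot be excluded by these values. A different mix of other cells left in the semen, which may give this pattern, and restricted feeding of the mother stay open as well, and neither was tested.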

How the results depend on the processing

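The alternatives marked as added (reads of 21 nt or more, length windows and DESeq2 factors for lists, and members named by sequence) were chosen after the results had been seen. No paired analysis was possible because the 3 tables of each group hold the same reads, so no replicate can be told apart. For the same reason a DESeq2 Wald test, leave-one-out fits, camera and fry, permutation of class shares and edgeR on class sums could not be run. A 15 to 45 nt window for sequences leaves the data as they are, since reads are 15 to 42 nt long.

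Log2 ratios of class shares are given with all reads as the denominator, without sequences of several classes, and with reads of 21 nt or more. For tRNA they were -1.09, -1.20 and -0.97 in OVER against CON, -0.62, -0.84 and -0.81 in RES against CON, and -0.47, -0.36 and -0.16 in OVER against RES. For miRNA they were 0.99, 0.90 and 1.14, then 0.47, 0.19 and 0.26, then 0.52, 0.72 and 0.88. For Y RNA they were -0.83, -0.94 and -0.64, then 1.06, 0.84 and 0.89, and in OVER against RES -1.89 with all reads and -1.53 at 21 nt or more.

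With all reads as the library size and no TMM factor, 49 miRNAs were at least 2-fold apart between OVER and CON and 53 between OVER and RES. The direction then turned for oar-let-7c (0.0765), oar-mir-103 (0.0915), oar-mir-107 (0.13) and oar-mir-323a (0.35) in OVER against CON, and for oar-mir-125b (0.0607), oar-mir-329b (0.18) and oar-mir-99a (0.0606) in OVER against RES. Between RES and CON, 10 tRNAs were at least 2-fold apart with DESeq2 size factors and 10 with no filter beyond 1 read. With no filter beyond 1 read, 101879 sequences were at least 2-fold apart between OVER and CON, 92674 between RES and CON and 121542 between OVER and RES.

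The let-7 median of OVER against RES was 0.0530 with DESeq2 size factors. The epithelial median of RES against CON was -0.93 with members named by sequence, and that of OVER against RES was 2.23 at 16 to 24 nt and 1.35 with members named by sequence. At 25 to 40 nt the mitochondrial tRNA median was 0.44 in RES against CON, and it turned to -0.99 in OVER against RES. The Glu-CTC 5′ fragment with deleted forms had log2 ratios of -2.74, -1.14 and -1.60 in OVER against CON, RES against CON and OVER against RES. The difference in mean length with annotated reads only and with each distinct sequence counted once was -5.04 and -5.78 nt in OVER against CON, -1.29 and -1.89 nt in RES against CON, and -3.74 and -3.89 nt in OVER against RES. Over sequences with a mean CPM of at least 10, the correlation of the 2 diet responses was 0.50, inside the simulated 0.48 to 0.52. The 25 to 40 nt window moved 27 of 28 named tRNA ratios.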

Other observations

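The tests in this part were chosen after the data had been seen. Unannotated reads hold a further set of small RNAs. Reads of 25 to 31 nt that matched the genome, had no annotation and did not share 14 nt with 5S or the 28S 5′ end made up 12.2% of all CON reads, 4.59% of OVER reads and 9.98% of RES reads. Of these, 70.1% in CON, 79.0% in OVER and 76.7% in RES began with T, against 30.5%, 30.2% and 32.2% of the unannotated genome-matching reads of 15 to 20 nt. Their size and first base are those of piRNAs, the germ line RNAs that silence transposons, so a candidate explanation is that they are piRNAs missing from the annotation. The lowest share with T over the libraries, 70.1%, fits that hypothesis, which was formed on the same data. Over distinct sequences the share with T was lower, at 48.3%, 58.7% and 53.0%.

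Pieces of 5S rRNA without annotation made up 1.85% of all reads in CON, 0.428% in OVER and 1.55% in RES, and reads of the 28S 5′ end 1.32%, 1.18% and 1.16%. Gly-GCC 5′ fragments also occurred with 1 base missing, at 19.6% of both forms in CON, 21.6% in OVER and 14.6% in RES. Over all tRNAs, reads that equal a tRNA read with 1 to 3 bases deleted were 7.90% of all reads in CON, 2.86% in OVER and 3.55% in RES. The valine tRNA 5′ fragment shared by Val-CAC and Val-AAC had 37.5% of its reads at 18 to 27 nt in CON, 72.5% in OVER and 74.9% in RES. Of 3309646 distinct sequences in the series, 139254 occurred in all 3 libraries, and these held 81.6%, 78.9% and 85.7% of the reads of CON, OVER and RES. Sequences seen once were 68.8%, 69.8% and 63.3% of the distinct sequences.

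Some miRNAs outside the ovine names differed from CON in both diet groups, which share the 1 CON library, so that its value alone can give the same direction in both. The folds are within the miRNA class, and in OVER against CON a miRNA's log2 ratio is 1.248 higher when scaled to all reads, so that the lower miR-92a there comes within 2-fold. MiR-184, which is high in testis, was 2.67-fold higher in OVER than in CON and 2.19-fold higher in RES, and miR-378, encoded within a regulator of mitochondrial metabolism, was 2.82-fold and 1.957-fold higher. MiR-92a was 3.40-fold and 2.51-fold lower. MiR-340 was 1.995-fold higher in RES and 1.24-fold higher in OVER. MiR-122, the main miRNA of liver, had 5 reads in CON, 5 in OVER and 75 in RES.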
